A study of Mus musculus with 22 samples.

How the data were processed

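Gene expression was measured in 22 colon tumours of male FVB/N mice, an inbred laboratory strain. The titles give each tumour its own mouse number, except an obese sulindac tumour titled Mouse_X, whose mouse number is not given. Per the labels, total RNA was isolated with TRIzol, copied into fragmented and biotin-labelled cDNA with the GeneChip WT PLUS kit, and hybridised to Clariom S arrays, which carry short probes grouped into probe sets that each represent a gene. The deposited values are levels on a scale read as log2, with 2 decimals, for 22203 probe sets on each of the 22 arrays. The submitters' processing notes name Transcriptome Analysis Console 4.0. The summarization of probes, the background correction, the normalization and the base of the logarithm are not given in the sources used here. Base 2 was taken from the range of the values, 3.34 to 19.49, so every difference stated in log2 units rests on that reading. Array medians lay between 6.67 and 6.83, which shows that the deposited log2 levels had been brought to a common scale. Normalization of that kind removes any difference in total RNA between tumours. It also makes each level relative to the rest of its array, and it gives no level above or below background for a single probe set.

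Gene names came from the array's annotation. Of the 22203 probe sets, 19572 carried 1 gene symbol, 0 carried several and 2631 are unnamed here. All 19572 named probe sets matched a gene of the mouse assembly GRCm38.p6 by Entrez identifier, and 0 symbols needed an update. These covered 19505 distinct symbols, of which 55 had more than 1 probe set, and a gene was then represented by its probe set with the highest mean over all arrays. On every array, 254 probe sets held values identical to another probe set's, so such genes cannot be separated from each other. All probe sets entered the tests, with no filter on dim signals. Control probes and raw scans were not used here.

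The groups were taken from the diet and sulindac labels. There were 6 control mice, 5 obese mice, 6 obese mice given sulindac and 5 formerly obese mice. The labels give no batch, litter or date, and no replicate numbers are shared between groups, so nothing pairs the mice. A linear model with a mean for each of the 4 groups was fitted to the log2 levels of all 22 arrays in R 4.3.3 with limma 3.58.1 (lmFit and eBayes), which lets all groups share an estimate of the spread. The 3 main comparisons were obese against control, formerly obese against obese, and obese sulindac against obese. The 3 other pairs of groups were secondary. A gene counted as changed at an adjusted p under 0.05 (Benjamini-Hochberg over the 22203 probe sets, two-sided), and an F test over the 4 groups was run the same way.

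The 40 gene lists, pathways and markers of cell types that colon tumours can hold, were fixed before the data were examined. A member without a probe set under its name was replaced by a measured gene that has this name as a synonym. In this way Pigq and Eno1b stood in for Gpi1 and Eno1 in glycolysis, and Tom1l2 for Srebf1 in fatty acid synthesis. These lists therefore do not hold only their intended genes. The score of a list in a mouse is the mean log2 level of its measured members. Scores were tested with the same limma model and adjusted over the 40 lists. Alternatives for the lists were camera with a preset correlation of 0.01 between members, camera with an estimated correlation, fry, and exact permutation tests of the scores. With 5 or 6 mice per group, the smallest p an exact test can give does not pass adjustment over 40 lists for a list changed alone. Intervals are 95% confidence intervals from the limma fit, SDs are between mice, and the value after ± beside a difference is its standard error. The share of the variance lying between groups was tested with 100000 permutations of the group labels. Correlations between 2 sets of log2 differences that use the same obese arrays were set beside 1000 random regroupings of the arrays after removal of the group means.

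The rule for named genes was also fixed beforehand. In each main comparison it takes, in each direction, the 10 largest changes past the threshold, filled up to 5 by the smallest unadjusted p where fewer pass. In a secondary comparison it takes the 3 largest rises and the 3 largest falls among those that pass. It adds up to 4 members with the smallest p from each list described, and always names a fixed set that includes Ptgs1, Ptgs2, Cpt1a, Pdk4, Angptl4, Lep, Adipoq, Mki67, Lgr5, Myc, Il1b, Il6 and Tnf. In every main comparison the described lists were fat oxidation, prostaglandin, inflammatory, cell cycle and WNT. The 5 lists with the smallest p in that comparison were added, so these were chosen from the same data. Predicted genes, Riken clones and olfactory or vomeronasal receptors are counted but not named. Ptgs1 has no named probe set and was not analysed here. Any other gene named in the text was chosen after its values were seen.

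The model was tested on simulated data. For genes, normal noise with each probe set's own mean and residual SD was drawn independently, and 200 genes were changed by a known fold in each run. For lists, the real arrays without their group means were regrouped at random, which keeps the correlation between genes, and each list was shifted alone. The gene results were recomputed with quantile normalization, with arrays centred on their medians, with probe sets above the median level only, with an intensity trend and robust prior, with only the 2 groups compared, with array weights, with the smooth muscle or the absorptive colonocyte score as a covariate, and without each mouse in turn. The list results were recomputed with quantile normalization, with members scaled to equal spread, with members above the median level only, and without each mouse in turn. The gene and list tests between pairs of groups were also recomputed without 3 mice that were doubted after their values were seen. These were control Mouse_20, obese Mouse_101 and formerly obese Mouse_134. The F test, the share of variance and the correlations of differences were not recomputed without them. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Precision is limited by the number of arrays. The median residual SD of a probe set was 0.35 log2 units, and a typical 95% interval reached 0.43 log2 units to either side of the difference between obese and control tumours.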

Results

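Azoxymethane is a carcinogen that gives rodents tumours of the colon. Expression was profiled in 22 such tumours from male mice on 4 regimens. The 6 control mice ate a low-fat diet with 10% of its energy from fat, and the 5 obese mice ate a high-fat diet with 60%. A further 6 obese mice on the high-fat diet were given sulindac, a non-steroidal anti-inflammatory drug that inhibits the cyclooxygenases. The 5 formerly obese mice were moved from the high-fat to the low-fat diet. The comparison of obese with control mice asks how tumours that grow under obesity differ. The other 2 main comparisons ask what dietary weight loss or sulindac does to the tumours of obese mice. Each array gave log2 levels for 22203 probe sets, with array medians of 6.67 to 6.83. The correlation between 2 arrays had a median of 0.977 and a highest value of 0.988, so no array repeated another. Single mice are named as in the sample titles, for example Mouse_134. The number of arrays limits the precision of every difference that follows.

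Tumours of the same group differed from each other about as much as tumours of different groups. The 4 groups accounted for 13.9% of the variance of all probe sets, against a mean of 14.3% when the group labels were permuted (permutation p = 0.533). The first principal component held 20.01% of the variance and the second 9.60%. Between the groups lay 6.61% of the first component (permutation p = 0.738) and 4.71% of the second (permutation p = 0.843). In limma's F test, 0 genes differed among the 4 groups at an adjusted p under 0.05, the smallest adjusted p being 0.755, while 1333 probe sets had an unadjusted p under 0.05. By chance alone 1110 would be expected.

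**Figure D1:**
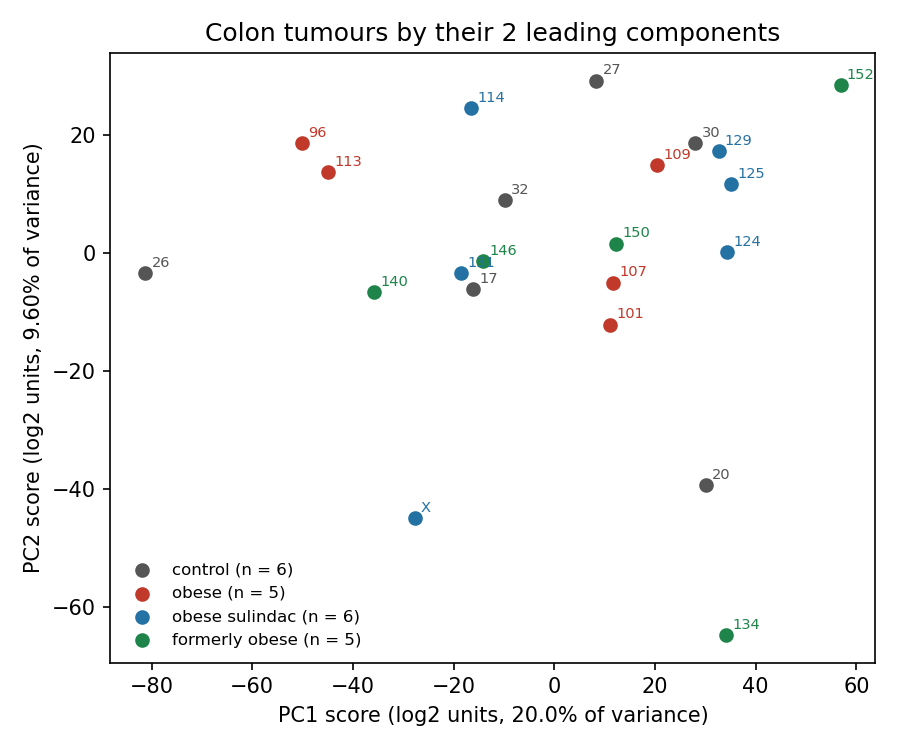
Scores of the 22 tumours on the first and second principal components of the log2 levels, in log2 units, with colours for the 4 groups and mouse numbers (or X) beside the points. The axes carry 20.01% and 9.60% of the variance, and the groups overlap on both.

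Obese tumours had higher mean levels of several genes that the endoplasmic reticulum uses to handle unfolded proteins, although no gene passed the test over all genes. Xbp1, which encodes a transcription factor of the unfolded protein response, was at 14.90 ± 0.24 in obese and 14.21 ± 0.27 in control tumours (log2 level, SD, n = 5 and 6). The difference was 0.69 ± 0.18 log2 units (95% interval 0.31 to 1.08), and 5 of 5 obese tumours lay above every control. Trib3, a pseudokinase gene induced by that response, differed by 0.63 ± 0.19 log2 units. Adjusted over the list alone, these 2 of the 19 measured members of the unfolded protein response list passed, at adjusted p = 0.0205 for Xbp1 and 0.0387 for Trib3, whereas over all genes 0 members passed (adjusted p = 0.9998 for both). That list was described because its p was among the 5 smallest in this comparison, and the list-alone values do not allow for that choice. Over all 240 combinations of list and comparison, 14 held such a call, against 12 expected if each list were a test of its own. Xbp1 also belongs to the list of B and plasma cell markers, where it passed adjusted over the list alone (adjusted p = 0.0173), and that list lay 0.37 higher in obese tumours (95% interval -0.41 to 1.15, adjusted p = 0.988, 13 of 16 members higher). The chaperone genes Dnajb9 and Dnajc3 differed by 0.51 ± 0.25 and 0.27 ± 0.15. Of the 19 members, 16 lay higher in obese tumours, and the list score was 12.48 ± 0.20 against 12.26 ± 0.13 (SD), a shift of 0.22 (95% interval -0.06 to 0.50) that did not pass (adjusted p = 0.988 in limma, exact p = 0.0649 before adjustment).

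Inflammatory genes were on average higher in obese tumours, with intervals that include no difference. In the list of inflammatory cytokines and NF-kB targets 22 of 23 members lay higher, and the score shifted by 0.71 (95% interval -0.26 to 1.69, adjusted p = 0.988). The cytokine genes Il1b, Il6 and Tnf differed by 0.83 ± 0.90, 0.88 ± 0.58 and 0.79 ± 0.52 log2 units, and Ccl2, which encodes a chemokine for monocytes, by 0.71 ± 0.40. Neutrophil markers shifted by 0.53 (95% interval -0.29 to 1.34, 13 of 16 members higher), including the collagenase gene Mmp8 at 1.16 ± 0.44. In the list of antimicrobial defence genes of the epithelium, 15 of 21 members lay higher and the score shifted by 0.60 (95% interval -0.38 to 1.57). Saa3, which encodes an acute-phase serum amyloid A protein, differed most clearly, at 11.24 ± 1.57 in obese and 9.08 ± 0.62 in control tumours (SD, n = 5 and 6). That is a difference of 2.17 ± 0.62 log2 units. It passed adjusted over the list alone (adjusted p = 0.0469) and not over all genes (adjusted p = 0.9998). The antimicrobial list was described for its small p, and the list-alone value does not allow for that choice. The list scores for neutrophils and antimicrobial defence did not pass either (adjusted p = 0.988 for both).

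Genes of fat oxidation, prostaglandin synthesis, proliferation and WNT signalling showed small average differences between obese and control tumours. The fatty acid oxidation and PPAR list shifted by -0.14 (95% interval -0.49 to 0.21) with 17 of 26 members lower, among them Ech1 at -0.54 ± 0.24 and the trifunctional protein genes Hadha at -0.49 ± 0.25 and Hadhb at -0.38 ± 0.20. Cpt1a, Pdk4 and Angptl4, which respond to fatty acids, differed by -0.10 ± 0.23, 0.75 ± 0.98 and -0.11 ± 0.25. The prostaglandin and leukotriene list shifted by -0.05 (95% interval -0.28 to 0.17). Ptgs2, the inducible cyclooxygenase gene, differed by 0.51 ± 0.77 and Hpgd, which encodes the enzyme that inactivates prostaglandins, by -1.75 ± 1.02. The cell cycle list shifted by 0.07 (95% interval -0.50 to 0.64) and the proliferation marker Mki67 by 0.30 ± 0.25. WNT targets and stem cell genes shifted by -0.01 (95% interval -0.70 to 0.68), with the stem cell marker Lgr5 at 0.91 ± 0.91 and Myc at -0.34 ± 0.24. Both adipocyte hormone genes lay near the bottom of the range in obese tumours, Lep at 4.34 ± 0.16 and Adipoq at 4.13 ± 0.29 (SD), with differences of -0.21 ± 0.21 and -0.07 ± 0.21. The squamous and anal epithelium list shifted by -0.33 (95% interval -0.87 to 0.20), with the keratin gene Krt4 at -1.80 ± 0.66, while its median member differed by 0.01. All 21 measured markers of absorptive colonocytes lay lower in obese tumours, by -0.45 on average (95% interval -1.57 to 0.67). Without obese Mouse_96 that shift was -0.11. These 6 lists had adjusted p = 0.988 in limma.

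By the smallest p, the genes that lay highest in obese against control tumours were Slc41a2, a magnesium transporter gene, at 1.33 ± 0.24 log2 units, Rhox5, a reproductive homeobox gene, at 1.09 ± 0.26, Tmem229b at 0.97 ± 0.26, Xbp1, and Apoa2, an apolipoprotein gene, at 0.56 ± 0.15. Those that lay lowest were Acbd4 at -1.03 ± 0.24, Tmem202 at -0.59 ± 0.14, Rab40c at -0.64 ± 0.15, Myoz1 at -0.56 ± 0.14 and Fam160b2 at -0.74 ± 0.20. Apoa2, Tmem202 and Myoz1 had means from 4.14 to 5.15 in the 2 groups, near the bottom of the range. Slc41a2 had the smallest adjusted p, 0.414, with 8.48 ± 0.36 in obese and 7.15 ± 0.41 in control tumours (SD, n = 5 and 6), and 5 of 5 obese tumours lay above every control. Limma called 0 genes changed between obese and control tumours. At an unadjusted p under 0.05 there were 894 probe sets, 403 higher and 491 lower, against 1110 expected by chance. Of the 40 lists, 0 changed in limma and 0 had an unadjusted p under 0.05. The same count of 0 came from fry and from camera with an estimated correlation (smallest adjusted p = 0.953). Exact permutation tests also gave 0, but could not call a list changed alone at these group sizes. Camera with a preset correlation called 5 lists higher. Those 5 were inflammatory cytokines, the unfolded protein response, macrophages and monocytes, neutrophils, and B and plasma cells, and none held with an estimated correlation (adjusted p = 0.953 for each).

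In the tumours of formerly obese mice, markers of mature absorptive colonocytes lay higher than in obese mice and several stem cell and matrix genes lay lower, again short of the threshold. All 21 measured absorptive colonocyte genes lay higher, and the score was 11.60 ± 1.22 against 10.38 ± 1.13 (SD, n = 5 and 5), a shift of 1.22 (95% interval 0.05 to 2.39, adjusted p = 0.388). The chloride exchanger gene Slc26a3 differed by 2.66 ± 1.10 log2 units and the carbonic anhydrase gene Car4 by 2.46 ± 1.17. Formerly obese Mouse_134 had the highest absorptive colonocyte score of all 22 tumours, 13.6 against 12.1 for the next, together with the highest smooth muscle score, 10.1 against 9.19. Without this mouse the shift was 0.72. These genes lay lower in obese than in control tumours, but both comparisons use the same 5 obese arrays. Opposite differences therefore arise without any effect of the diet switch. Immediate early and dissociation genes, which respond to tissue handling, also lay higher, by 0.66 (95% interval -0.27 to 1.60, adjusted p = 0.515; 0.22 without Mouse_134). Hpgd, which is abundant in differentiated epithelium, differed by 2.37 ± 1.07. Bile acid and FXR genes shifted by 0.48 (95% interval 0.03 to 0.92, adjusted p = 0.388), and by 0.22 without Mouse_134. Among them were Slc51b, which encodes a subunit of the bile acid exporter, at 1.15 ± 0.36 and Nr1h4, the gene of the bile acid receptor FXR, at 1.48 ± 0.78. Cyp7a1, the rate-limiting enzyme of bile acid synthesis in the liver, was at 5.49 ± 0.48 against 4.67 ± 0.25 (SD), low in the range of levels, with a difference of 0.81 ± 0.19.

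Lgr5 was at 9.79 ± 1.75 in formerly obese and 12.25 ± 0.84 in obese tumours (SD, n = 5 and 5), a difference of -2.46 ± 0.95 log2 units (95% interval -4.44 to -0.47), and 4 of 5 formerly obese tumours lay below every obese tumour. The WNT antagonist gene Wif1, itself a WNT target, differed by -1.81 ± 0.75. The WNT target list as a whole shifted by -0.46 (95% interval -1.18 to 0.26, adjusted p = 0.559), with 15 of 19 members lower. Genes of the epithelial-mesenchymal transition list shifted by -0.60 (95% interval -1.20 to -0.01, adjusted p = 0.388), with 19 of 23 lower, such as Tgfb3 at -1.42 ± 0.45, the collagen cross-linking enzyme gene Lox at -1.57 ± 0.64 and the fibronectin gene Fn1 at -1.07 ± 0.45. Among stromal markers, fibroblast and extracellular matrix genes lay lower by -0.40 (95% interval -0.89 to 0.08, adjusted p = 0.447) and endothelial genes by -0.36 (95% interval -0.90 to 0.17, adjusted p = 0.522). Smooth muscle genes lay higher by 0.28 (95% interval -0.32 to 0.88, adjusted p = 0.865; -0.08 without Mouse_134), and markers of enteric neurons and glia by 0.19 (95% interval -0.03 to 0.41, adjusted p = 0.447). Insulin and IGF signalling genes shifted by -0.30 (95% interval -0.60 to 0.00, adjusted p = 0.388). In that list the growth factor gene Igf1 differed by -1.10 ± 0.47 (-0.71 without obese Mouse_113) and the genes of its binding proteins Igfbp4 and Igfbp7 by -1.37 ± 0.50 and -0.71 ± 0.28. The 4 red blood cell markers were all lower, by -0.50 on average (95% interval -0.997 to -0.007, adjusted p = 0.388, exact p = 0.0159 before adjustment), led by the haem synthesis gene Alas2 at -1.46 ± 0.63. Epb42 differed by -0.36 ± 0.17, while Slc4a1 at -0.11 ± 0.33 and Hemgn at -0.08 ± 0.20 hardly differed. The average therefore rests mainly on Alas2. Adjusted over the list alone, 0 members of these lists passed in this comparison.

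Fat oxidation, prostaglandin, inflammatory and cell cycle lists had intervals that include no difference between formerly obese and obese tumours. The shifts were 0.07 (95% interval -0.30 to 0.43), -0.02 (95% interval -0.26 to 0.21), -0.37 (95% interval -1.39 to 0.65) and 0.05 (95% interval -0.55 to 0.64), with adjusted p = 0.923 for each. Hsd17b4, a gene of peroxisomal fatty acid oxidation, differed by -0.50 ± 0.16, Angptl4 by -0.60 ± 0.26 and Pdk4 by -0.88 ± 1.02. Ptgs2 differed by -0.26 ± 0.80, Il1b by -0.78 ± 0.94, Il6 by -0.51 ± 0.60, Tnf by -0.13 ± 0.54, Mki67 by 0.17 ± 0.26, Myc by -0.16 ± 0.25 and Cpt1a by 0.16 ± 0.24. Lep and Adipoq differed by 0.18 ± 0.22 and 0.29 ± 0.22.

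The smallest p values belonged to Vstm2a, Fam217a, Cyp7a1, Prss43 and Ucn among genes higher in formerly obese tumours, with differences of 0.58 to 0.81 log2 units, all at means of 5.49 or less in the formerly obese group, near the bottom of the range. Among genes lower in formerly obese tumours they belonged to Adam4, Csf1, St3gal2, Fbln5 and Rhox5. Csf1, which encodes the growth factor of macrophages, differed by -1.24 ± 0.29, the elastic fibre gene Fbln5 by -1.75 ± 0.45, and Rhox5 by -1.04 ± 0.27. All 10 had adjusted p = 0.866. Limma called 0 genes changed between formerly obese and obese tumours, while 1263 probe sets had an unadjusted p under 0.05, 616 higher and 647 lower, against 1110 by chance. It called 0 of the 40 lists, 5 of which had an unadjusted p under 0.05. Fry, exact permutation tests (smallest adjusted p = 0.317) and camera with an estimated correlation (smallest adjusted p = 0.625) called 0 lists. The exact test could not have called a list changed alone at these group sizes. Camera with a preset correlation called 10, 5 higher and 5 lower, none of which held with the estimated correlation.

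The unfolded protein response genes Xbp1, Trib3 and Dnajb9 had lower mean levels in tumours of obese mice given sulindac than in those of obese mice without the drug, and none passed the test over all genes. Xbp1 was at 14.23 ± 0.32 with sulindac and 14.90 ± 0.24 without (SD, n = 6 and 5), a difference of -0.68 ± 0.18 log2 units. Dnajb9 differed by -0.86 ± 0.25, with 6 of 6 treated tumours below every untreated obese tumour, and Trib3 by -0.52 ± 0.19. Adjusted over the list alone, Xbp1 and Dnajb9 passed (adjusted p = 0.0212 for both), and over all genes 0 of the 19 members did (adjusted p = 0.579 and 0.588). Here too the list was described for its small p, and the list-alone values do not allow for that choice. The list score shifted by -0.28 (95% interval -0.56 to 0.00, adjusted p = 0.764, exact p = 0.0823 before adjustment), with 16 of 19 members lower. These genes lay higher in obese than in control tumours, but both comparisons use the same 5 obese arrays, so opposite differences arise without any effect of the drug. A reversal was not tested for these genes alone.

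In the fatty acid oxidation and PPAR list, the peroxisomal thiolase gene Acaa1b differed by -0.82 ± 0.22 and Angptl4, which encodes an inhibitor of lipoprotein lipase, by -0.88 ± 0.25 between sulindac-treated and untreated obese tumours. Adjusted over the list alone both passed (adjusted p = 0.0240), and over all genes neither did (adjusted p = 0.579). Acaa1b was lower in 6 of 6 treated tumours than in every untreated one, and Angptl4 in 5 of 6. The lipid droplet gene Plin2 differed by -0.43 ± 0.20, while Hadhb differed by 0.35 ± 0.20, Cpt1a by -0.06 ± 0.23 and Pdk4 by -0.74 ± 0.98. Without obese sulindac Mouse_X the Pdk4 difference was -1.76, and without obese sulindac Mouse_114 that of Cpt1a was 0.11. The list as a whole shifted by -0.06 (95% interval -0.41 to 0.29, adjusted p = 0.930), with 12 of 26 members higher and 14 lower. Oxidative phosphorylation genes lay slightly higher with sulindac, 22 of 27 of them, by 0.18 on average (95% interval -0.07 to 0.42, adjusted p = 0.764). The ATP synthase genes Atp5a1 and Atp5o differed by 0.39 ± 0.12 each, with 6 of 6 treated tumours above every untreated one. In the adipocyte marker list Pnpla2, the gene of the lipase that starts triglyceride breakdown, differed by 0.61 ± 0.15, and it was the only member to pass adjusted over the list alone (adjusted p = 0.0104; 0.567 over all genes).

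Prostaglandin genes, the pathway sulindac acts on, included Ptgs2 at 9.05 ± 1.43 with sulindac and 10.28 ± 0.83 without (SD, n = 6 and 5). The difference was -1.24 ± 0.77 log2 units (95% interval -2.83 to 0.36, adjusted p = 0.832). Ptges, the gene of the inducible prostaglandin E synthase, differed by -0.74 ± 0.35. The whole list shifted by 0.03 (95% interval -0.19 to 0.26, adjusted p = 0.930). Among inflammatory genes the cytokine genes Il11 and Il6 differed by -3.60 ± 1.06 and -1.21 ± 0.58, and Ccl2 by -0.99 ± 0.40, while Il1b differed by -0.62 ± 0.90 and Tnf by -0.45 ± 0.52. Il11 had the largest difference of these, at 6.41 ± 1.64 against 10.01 ± 1.56 (SD), and its adjusted p was 0.588. The inflammatory list shifted by -0.39 (95% interval -1.37 to 0.58, adjusted p = 0.764), by -0.71 without obese sulindac Mouse_114 and by -0.07 without Mouse_X. The matrix metalloproteinase genes Mmp10, Mmp13 and Mmp3, members of the epithelial-mesenchymal transition list, differed by -2.26 ± 0.68, -2.73 ± 0.9997 and -1.68 ± 0.80, while Tgfbi, a matrix protein gene of that list, differed by 0.56 ± 0.24. The list shifted by -0.48 (95% interval -1.05 to 0.10, adjusted p = 0.764), with 8 members higher and 15 lower.

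Of 27 cell cycle genes, 26 lay higher with sulindac, by 0.27 on average (95% interval -0.30 to 0.84, adjusted p = 0.764), with Mki67 at 0.49 ± 0.25. Without obese Mouse_113 the average was 0.14. WNT targets and stem cell genes shifted by -0.27 (95% interval -0.96 to 0.42, adjusted p = 0.764), with Sox9 at -0.63 ± 0.25, Lgr5 at -1.70 ± 0.91, Wif1 at -1.23 ± 0.72 and Myc at -0.15 ± 0.24. Absorptive colonocyte genes shifted by 0.73 (95% interval -0.39 to 1.84, adjusted p = 0.764), with 19 of 21 higher, and by 0.39 without obese Mouse_96. The 4 red blood cell markers shifted by -0.46 (95% interval -0.93 to 0.02, adjusted p = 0.764). That shift rests mainly on Alas2 at -1.45 ± 0.61, with Epb42 at -0.26 ± 0.16, Slc4a1 at -0.11 ± 0.31 and Hemgn at -0.01 ± 0.19. Lep and Adipoq differed by 0.31 ± 0.21 and 0.22 ± 0.21.

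**Figure D2:**
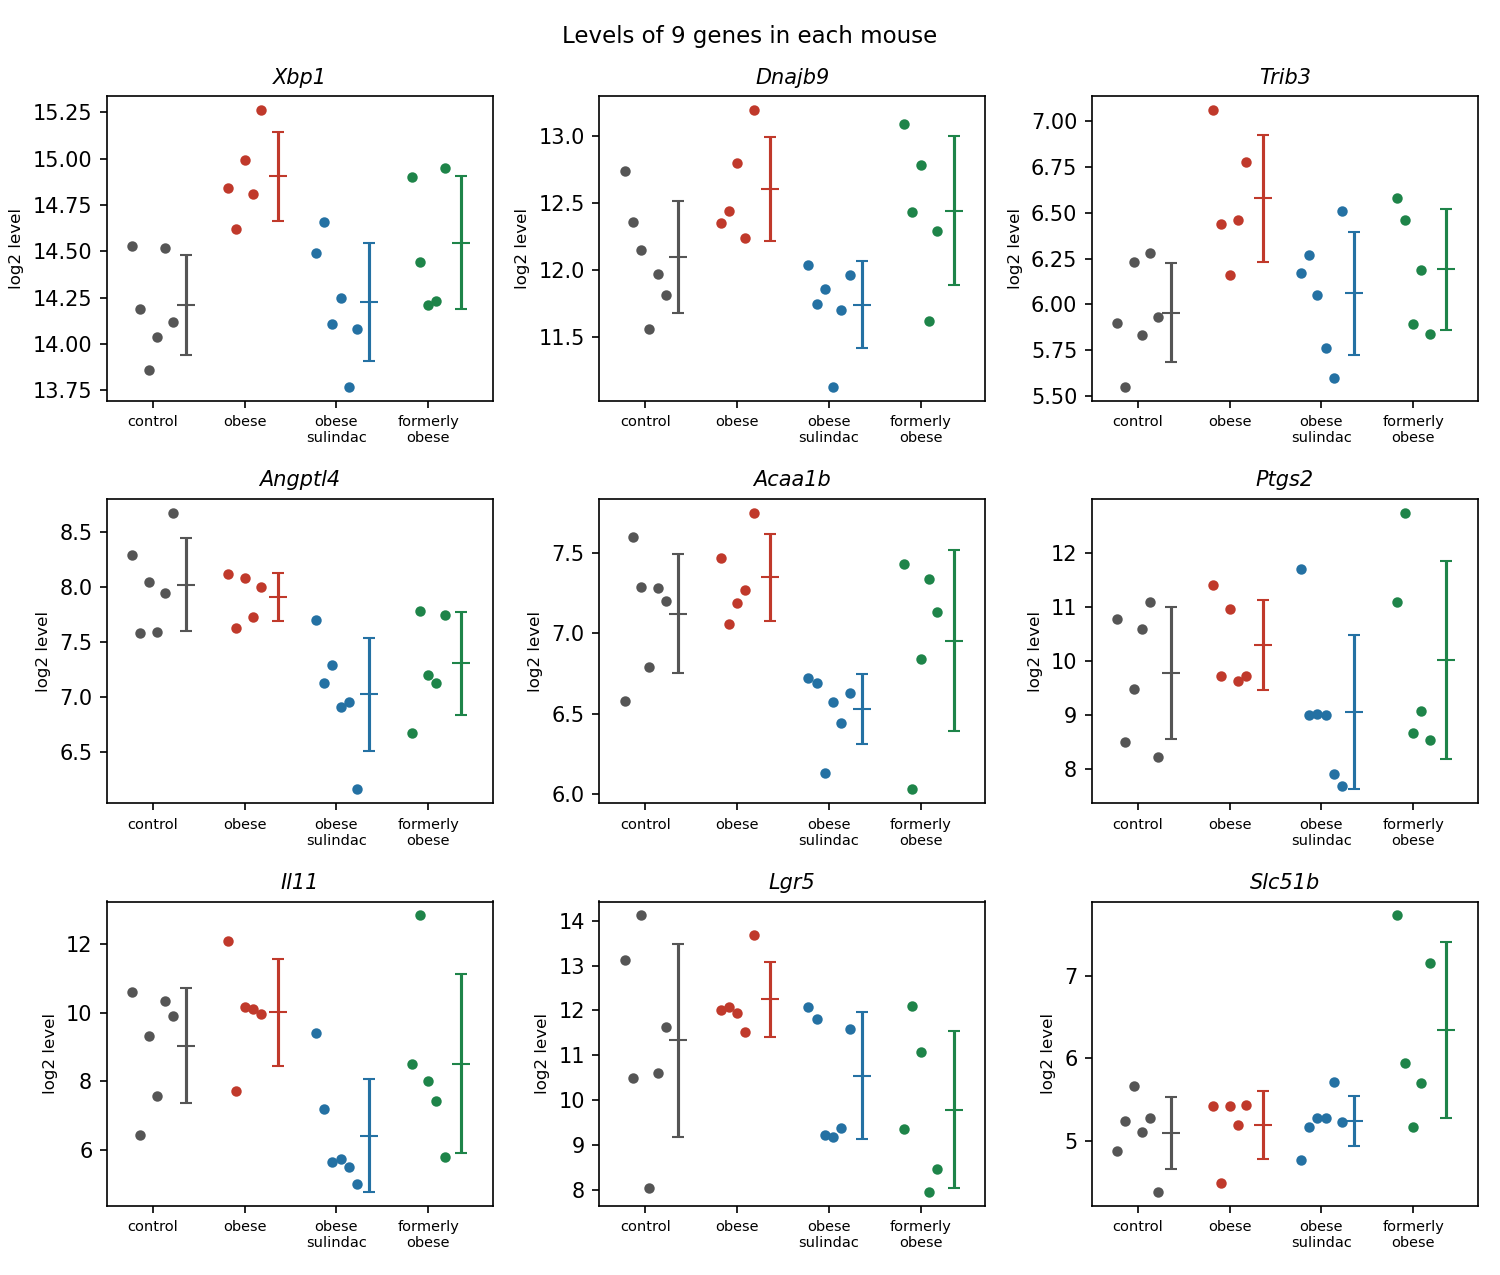
Log2 levels of 9 genes in each of the 22 tumours, with 1 point per mouse and the group mean and SD beside the points, on axes that do not start at 0. Xbp1 lies above every control in 5 of 5 obese tumours, and Dnajb9 and Acaa1b lie below every untreated obese tumour in 6 of 6 sulindac-treated tumours, while none of the 9 genes passed the test over all genes.

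By the smallest p, the genes that lay highest with sulindac were Psph, a serine synthesis gene, at 0.76 ± 0.16, Grk6 at 0.81 ± 0.18, Ccl21a at 1.92 ± 0.43, Mmrn1 at 1.32 ± 0.30 and Ccl21b at 2.14 ± 0.49. Ccl21a and Ccl21b encode a chemokine of lymphatic vessels and lymph nodes, and Mmrn1 is expressed in lymphatic endothelium. The values of Ccl21b are identical to those of Ccl21c on every array, so these 2 copies cannot be told apart. The genes that lay lowest were Pole4 at -0.97 ± 0.21, the zinc finger genes Zfp458 at -0.91 ± 0.21, Zfp160 at -0.69 ± 0.16 and Zfp830 at -0.65 ± 0.16, and Tsnax at -0.76 ± 0.18. Their adjusted p values ran from 0.533 to 0.555. Without obese Mouse_96, Pole4, a gene of a DNA polymerase epsilon subunit, passed the test at -1.20 log2 units (adjusted p = 0.0220), and it was the only gene to do so (smallest adjusted p of 0.0220 to 0.985 as each mouse in turn was left out). With all mice limma called 0 genes changed between sulindac-treated and untreated obese tumours, while 1454 probe sets had an unadjusted p under 0.05, 682 higher and 772 lower, against 1110 by chance. It called 0 of the 40 lists, and 0 had an unadjusted p under 0.05. Fry, exact permutation tests (smallest adjusted p = 0.563) and camera with an estimated correlation (smallest adjusted p = 0.869) called 0 lists. Here too the exact test could not have called a list changed alone. Camera with a preset correlation called 7, 6 higher and 1 lower, the latter being the unfolded protein response, and none held with the estimated correlation (adjusted p = 0.869 for each).

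**Figure D3:**
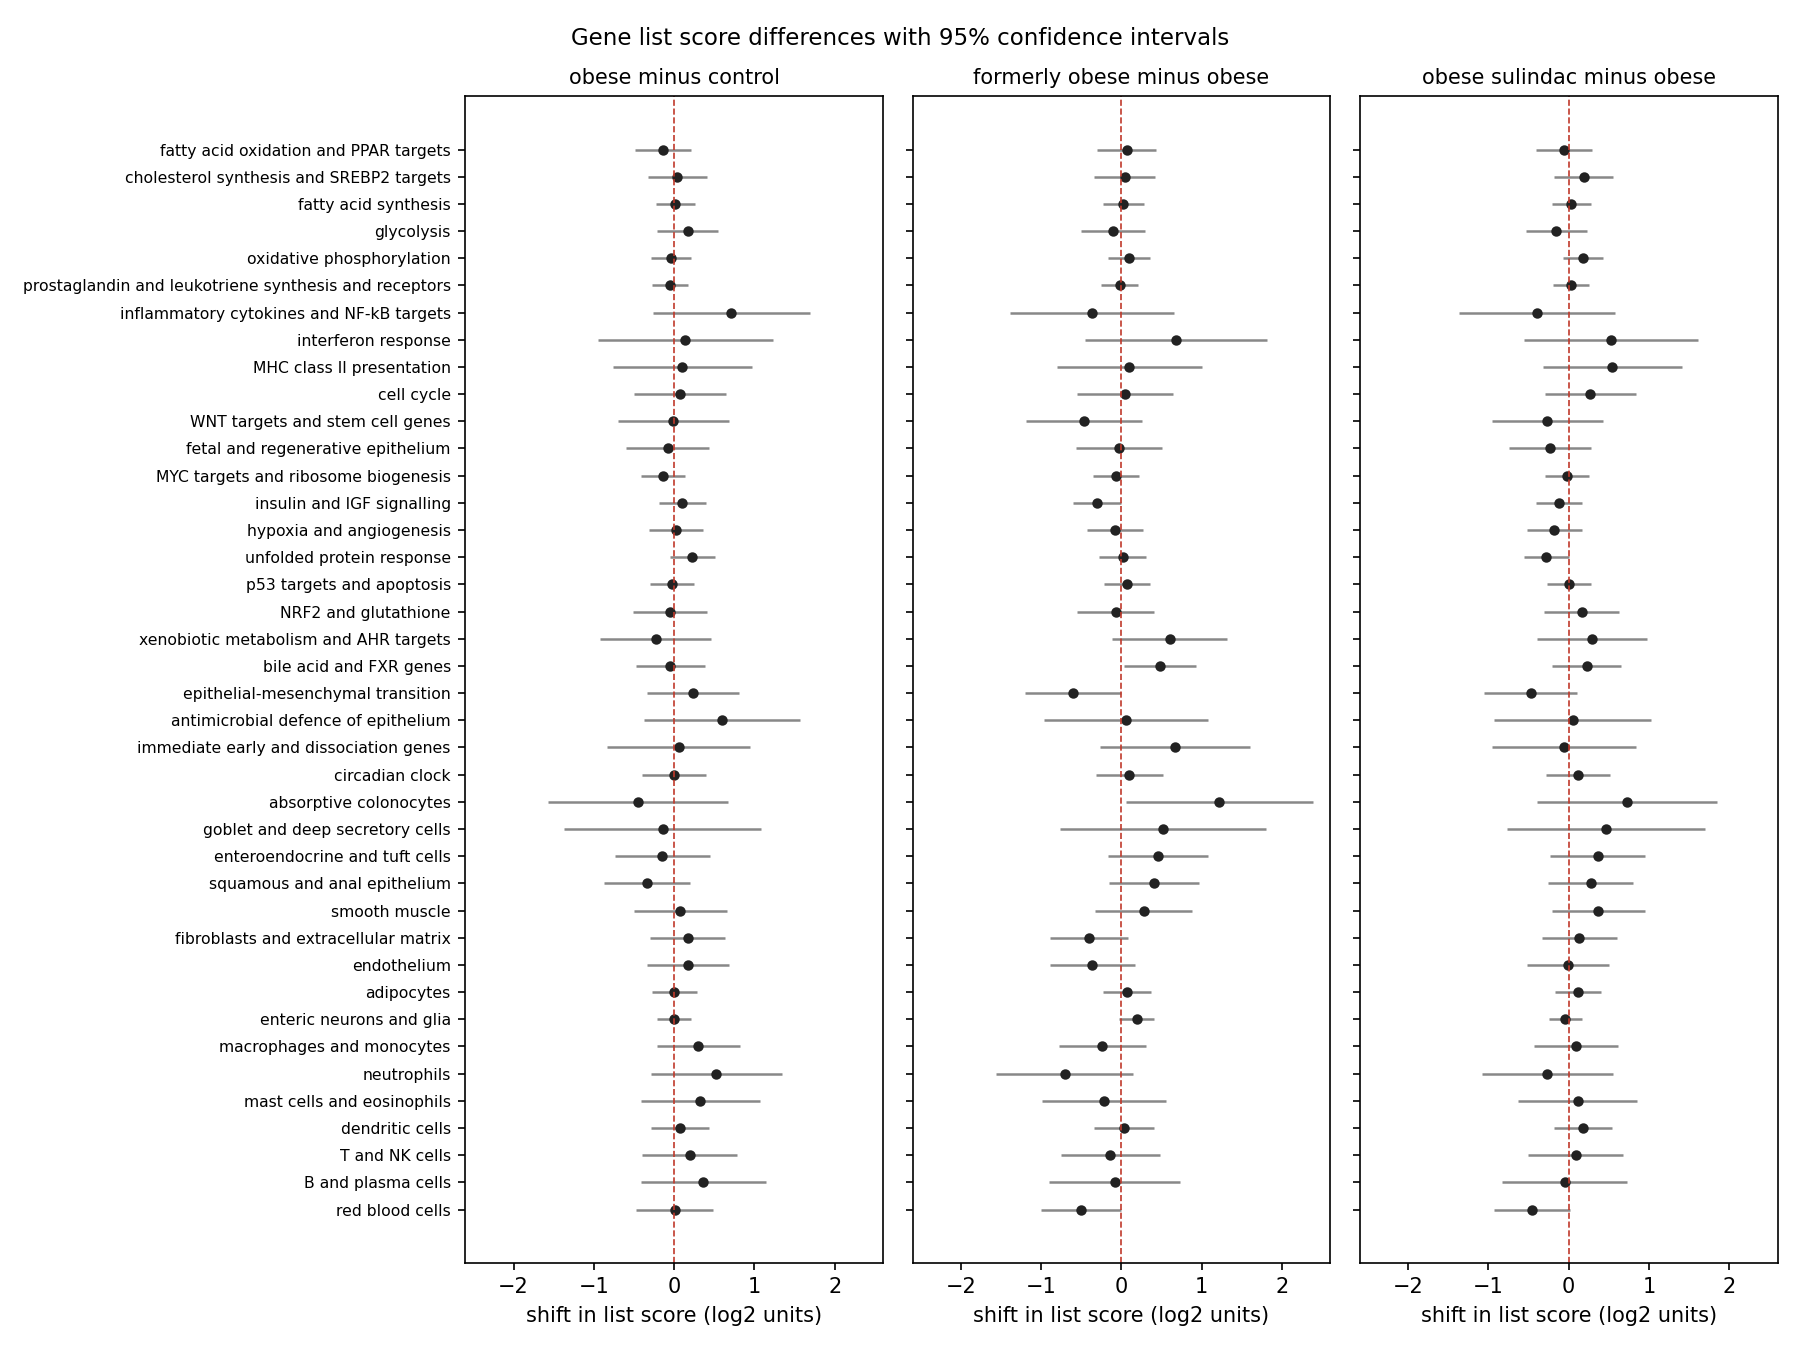
Differences in the score of each of the 40 gene lists, in log2 units, for the 3 main comparisons, with points for the difference between group means and lines for the 95% confidence interval. The longest shift is that of absorptive colonocytes between formerly obese and obese tumours, 1.22 (0.05 to 2.39), and no list passed adjustment over the 40 lists.

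The secondary comparisons gave the same result at the threshold. Limma called 0 genes between formerly obese and control tumours, 0 between sulindac-treated obese and control tumours, and 0 between formerly obese and sulindac-treated obese tumours. At an unadjusted p under 0.05 there were 1231, 1473 and 1470 probe sets, and the smallest adjusted p values were 0.263, 0.450 and 0.548. Without formerly obese Mouse_152, Defb10, a beta-defensin gene, passed between formerly obese and control tumours at 1.04 log2 units (adjusted p = 0.0465). With all mice its difference was 0.88 ± 0.17 (adjusted p = 0.263). Limma, fry, exact permutation tests and camera with an estimated correlation called 0 lists in each of the 3, while 1, 0 and 3 lists had an unadjusted p under 0.05 in limma and camera with a preset correlation called 9, 12 and 6. In single lists some genes passed adjusted over the list alone. Against controls, Angptl4 differed by -0.997 ± 0.24 with sulindac (adjusted p = 0.0102), Sox9 by -0.96 ± 0.24 (adjusted p = 0.0125) and Cd44 by -0.77 ± 0.23 (adjusted p = 0.0326). In the same comparison Atp5o differed by 0.45 ± 0.115 (adjusted p = 0.0203). Slc51b differed by 1.25 ± 0.35 between formerly obese and control tumours (adjusted p = 0.0196), and Ptges2, which encodes a prostaglandin E synthase, by -0.69 ± 0.18 (adjusted p = 0.0174). Between formerly obese and sulindac-treated obese tumours, Ptges2 differed by -0.70 ± 0.18 (adjusted p = 0.0142) and Adipor2 by 0.58 ± 0.16 (adjusted p = 0.0293). Over the 240 combinations of list and comparison, 14 held such a call, against 12 that chance would give if each list were a test of its own. In 30 of the 240 the mean and the median of the members differed in sign, and in 17 the mean and camera's direction did.

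The differences between obese and control tumours and those between formerly obese and obese tumours correlated at r = -0.516 across all probe sets, which are not independent of each other. Both differences contain the same 5 obese arrays, and regrouped arrays with no group effect gave a mean r of -0.521 (95% of regroupings between -0.755 and -0.196, permutation p = 0.957). For sulindac the correlation was -0.491, against -0.538 in regrouped arrays (permutation p = 0.731). The last pair was formerly obese against obese and sulindac-treated against untreated obese tumours. Their differences correlated at 0.558, against 0.511 in regrouped arrays (permutation p = 0.732). The covariances exceeded those of the regrouped arrays by 0.0078, 0.0133 and 0.0047. With the obese arrays split so that no array was shared, the 3 correlations were -0.0148, 0.0271 and 0.0873 (permutation p = 0.871, 0.911 and 0.525). A reversal of the obesity profile by weight loss or by sulindac, or a likeness of the 2 interventions, was therefore not detectable over all genes in these arrays.

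Simulated changes show which sizes these group sizes could reveal on average. With 200 of 22203 probe sets changed, the same test recovered 57.0% of 2-fold and 93.5% of 4-fold changes between obese and control tumours. Between formerly obese and obese tumours it recovered 46.0% and 90.5%, and between sulindac-treated and untreated obese tumours 62.0% and 89.0%. A shift of 1 log2 unit in a list score was recovered in 61.4%, 52.9% and 59.1% of simulated cases, and a shift of 0.5 in 18.3%, 15.5% and 18.3%. The recovery of single genes would be lower if fewer genes changed, since the adjustment depends on how many do. The recovered shares are averages over probe sets and lists of differing spread. They overstate the recovery for noisy ones, such as Lgr5 (standard error 0.91 between obese and control tumours) and absorptive colonocytes (within-group SD 0.94). Single mice also weighed on the list shifts. Leaving out 1 mouse changed the shift by more than 1.5 times, or its sign, in 37 of 40 lists between obese and control tumours, in 33 between formerly obese and obese tumours, and in 34 between sulindac-treated and untreated obese tumours. The unfolded protein response list was among them only between formerly obese and obese tumours, and its shift ran from 0.17 to 0.29 between obese and control tumours and from -0.36 to -0.22 with sulindac. It was not alone in this. The inflammatory list between obese and control tumours (0.48 to 0.95) and oxidative phosphorylation genes with sulindac (0.15 to 0.21) were also not among them. Shifts near 0, such as -0.01 for WNT targets between obese and control tumours, enter these counts easily.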

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

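The tests of the Hoxd neighbours of Hoxd13, of the posterior Hox genes outside Hoxd and of formerly obese Mouse_134 were chosen only after the results were seen. The tests of the other posterior Hox genes, of lymphatic and follicle markers, and of the smallest p were written before those results were seen.

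Tumours from control Mouse_20 and obese Mouse_101 hardly expressed Hoxd13, a homeobox gene of the most distal gut, at 4.65 and 5.09 on the log2 scale against 10.59 to 14.68 in the other 20 tumours. A failed probe set on these 2 arrays is argued against by the neighbouring genes Hoxd10, Hoxd11 and Hoxd12, whose mean was 5.03 and 6.20 against 9.19 ± 1.19 (SD) elsewhere, a z score of -2.53 for the nearer of the 2 mice. A more proximal site of the tumour may lie behind the pattern, since the 6 other posterior Hox genes scored 6.69 and 7.05 (lowest other 7.10, z score of -1.91 for the nearer mouse), but the 3 Hoxd genes, and in Mouse_101 also Hoxb13, made that score low. The 3 outside Hoxd scored 8.36 and 7.90 against 7.44 ± 0.46 (SD) elsewhere, with Hoxa13 above every other mouse in both (9.0 and 9.05), Hoxa11 above every other in Mouse_101 alone (7.90), and Hoxb13 below every other in Mouse_101 (6.75) and near the mean in Mouse_20 (10.22 against 10.35). These genes point in different directions and the site is not in the labels, so this stays open, and no biological explanation tied to the groups was tested.

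The absorptive colonocyte score was higher in formerly obese than in obese tumours by 1.22, and formerly obese Mouse_134 alone carried part of that shift. Without this mouse 0.592 of the shift was left (0.72 ± 0.58 log2 units, exact p = 0.317 against 0.175 with it). Mouse_134 also had the highest smooth muscle score of the 22 mice and the highest score of immediate early and dissociation genes, which respond to tissue handling (12.2 against 11.7 in the next), and its level of Cyp2c55, a cytochrome P450 gene, was 15.77 against 8.76 in the next mouse, so normal mucosa and muscle in its tissue could be a source. Its WNT and stem cell score of 11.2 ranked 3 of 5 in its group, which does not single it out as poor in tumour cells. More differentiated epithelium after the diet switch may also contribute. Of 5 formerly obese mice, 4 lay above the obese median, but Mouse_134 is among them and so few mice can fall that way by chance. The 2 explanations cannot be told apart with 5 mice per group.

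Ccl21a and Mmrn1 were higher in tumours of obese mice given sulindac than in obese mice by 1.92 ± 0.43 and 1.32 ± 0.30, and higher than in controls by 1.68 ± 0.41 and 1.19 ± 0.28. Selection by chance is a candidate explanation, since 52 of 100 splits of the mice gave a smallest p over all probe sets at least as low as the smallest of the real split, which belongs to an unnamed probe set and is lower than those of Ccl21a and Mmrn1. A list of 10 other lymphatic vessel genes shifted by 0.16 against obese mice (exact p = 0.600), and a list of lymphoid follicle genes by 0.02 (exact p = 0.944). The lymphatic list holds Tbx1, which ranged from 7.36 to 14.55 over the tumours, so part of the spread of that score may come from this gene. Against controls the same lists shifted by 0.38 and 0.37 (exact p = 0.247 and 0.160), and none of the 4 tests passed adjustment (smallest adjusted p = 0.494). More lymphatic vessels or follicles therefore cannot be told apart from no change, given the spread of these scores.

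Single tumours far from the others of their group appeared in 38 of 452 tests of a gene or list in a group, where chance gives about 1 in 20. Some genes were named because single tumours had extreme values, and Ccl21b and Ccl21c count as separate genes, so part of the excess is built in. Among metabolic and bile acid genes, obese sulindac Mouse_X had Pdk4 at 13.82 (next 8.65) and obese sulindac Mouse_114 had Cpt1a at 10.92 (next 11.87). Hadha was at 14.98 in control Mouse_20 (next 14.42) and at 12.82 in obese Mouse_96 (next 14.11). Adipoq was at 5.27 in formerly obese Mouse_134 (next 4.36), and Slc51b at 4.48 in obese Mouse_101 (next 5.19). Bile acid and FXR scores stood apart in formerly obese Mouse_134 at 7.76 (next 6.71) and in obese sulindac Mouse_114 at 5.94 (next 6.50). Igf1, Lgr5 and Ucn were high in obese Mouse_113, at 17.72 (next 15.90), 13.69 (next 12.07) and 4.92 (next 4.55). Without the mouse that stood apart, the difference between formerly obese and obese tumours was 0.08 for Adipoq instead of 0.29. Between obese and control tumours that of Hadha was -0.23 without Mouse_96 instead of -0.49, and that of Lgr5 0.55 without Mouse_113 instead of 0.91.

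Inflammatory and matrix genes gave several such values in obese sulindac Mouse_114, which had Mmp13 at 15.28 (next 11.92), Mmp3 at 9.81 (next 7.08), Ptgs2 at 11.69 (next 9.01) and an epithelial-mesenchymal transition score of 11.31 (next 10.40). The other 5 treated mice therefore averaged below the group means given for these genes. The prostaglandin score was 9.34 in obese sulindac Mouse_131 (next 9.05), and without it the sulindac shift of that score was -0.03 instead of 0.03. Ptges was 7.85 in formerly obese Mouse_134 (next 9.06). Il6 was 8.10 in formerly obese Mouse_140 (next 5.69), without which its difference from obese tumours was -1.08 instead of -0.51, and the neutrophil score 7.25 in formerly obese Mouse_152 (next 6.35). Tgfb3 was 6.08 (next 7.37) and Dnajb9 11.13 (next 11.70) in obese sulindac Mouse_129.

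Genes of tissue identity stood apart in control Mouse_20, with Krt4 at 5.95 (next 7.95), Hoxd11 at 4.40 (next 10.28) and Cyp2c55 at 8.76 (next 6.29). Cyp2c55 was 15.77 in formerly obese Mouse_134 (next 7.17). In obese Mouse_101, Hoxa11 was 7.90 (next 5.65), Hoxb13 6.75 (next 9.71) and Hoxd13 5.09 (next 12.54). Hoxd13 was 12.30 in obese sulindac Mouse_131 (next 13.75). Control Mouse_26 had Bpifb1 at 15.88 (next 8.37), Pkd2l1 at 11.82 (next 6.27) and Ccl21b and Ccl21c at 7.04 (next 8.41). Among the genes picked by their p, Acbd4 was 7.42 in obese Mouse_96 (next 6.59), Rhox5 was 5.21 in obese sulindac Mouse_131 (next 6.23) and Vstm2a was 4.76 in control Mouse_27 (next 4.24). Pole4 was 12.60 in control Mouse_32 (next 12.30) and 11.99 in obese sulindac Mouse_124 (next 11.83).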

How the results depend on the processing

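The alternative that leaves out 3 doubted mice was chosen after seeing the data. Under quantile normalization, median centring, a filter on levels, a trended prior, pairwise fits, array weights and the smooth muscle or absorptive colonocyte covariates, limma called 0 genes in all 6 comparisons, as with all mice. A criterion without adjustment, an unadjusted p under 0.05 with a change of at least 2-fold, gave 44 genes for obese against control, 1.5e+02 (60 higher and 92 lower) for formerly obese against obese, 111 for obese sulindac against obese, 94 for formerly obese against control, 104 for obese sulindac against control and 106 for formerly obese against obese sulindac. Camera with a preset correlation called 5, 10, 7, 9, 12 and 6 lists in the same order, and 0 with an estimated correlation, so the assumed correlation between members is what separates them. Leaving out single mice gave 0 to 1 genes for obese sulindac against obese (Pole4 without obese Mouse_96) and 0 to 1 for formerly obese against control (Defb10 without formerly obese Mouse_152), and 0 elsewhere. Among this many refits such calls can arise by chance, and whether these 2 mice matter was not tested. Without the 3 doubted mice, 0 genes and 0 lists were called. Over 3332 recalculated values of 172 named gene results, 1 passed the threshold and 32 changed sign without passing. Over 510 recalculated values of 29 list results, other than those of camera with a preset correlation, 0 passed. With that setting counted as well, 23 list values changed sign without passing. The sign changes concerned differences near 0, such as Cpt1a in all 3 main comparisons, Ptgs2 and Mki67 between formerly obese and obese tumours, and the WNT and cell cycle lists between obese and control tumours. For 38 lists at least 3 members lay above the median level, and the filter on levels was applied to those alone. The deposited levels give no background, so the weakest probe sets could not be set apart by signal over background.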

Other observations

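The 3 correlation tests below were chosen after the results were seen, while the counts over other splits of the mice were planned.

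Single tumours of the same regimen differed widely in genes of cell identity and defence. Sox2, a transcription factor gene of the foregut, ranged from 4.94 in formerly obese Mouse_134 to 15.19 in obese Mouse_113. Cdx2, which encodes a transcription factor of intestinal identity, ranged from 5.92 to 13.64. Within the controls alone Sox2 spanned 6.15 to 14.44 and Cdx2 7.11 to 13.64. Bpifb1, a gene of a secreted mucosal protein, ranged from 4.38 to 15.88, and Otop1 and Pkd2l1, a proton channel gene and a cation channel gene of sour taste cells, from 6.87 to 15.52 and from 4.36 to 13.29. The antimicrobial lectin genes Reg3b and Reg3g spanned 6.03 to 17.18 and 5.78 to 17.20, with both extremes in control Mouse_26 and Mouse_27. Ido1, which encodes a tryptophan-degrading enzyme, ranged from 4.83 to 13.50 and Nos2, the inducible nitric oxide synthase gene, from 5.97 to 12.56.

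Among the 40 lists, the scores that spread most within groups were those of goblet and deep secretory cells (SD 1.04), absorptive colonocytes (0.94), interferon response (0.91), antimicrobial defence (0.82) and inflammatory cytokines (0.82). The first principal component correlated at -0.866 with the WNT and stem cell score and at 0.787 with the antimicrobial score over the 22 tumours.

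A hypothesis from these values is that the tumours differ along an axis from WNT activity to epithelial defence, which may cut across the regimens. Immune infiltration may belong to it, since the MHC class II and T and NK cell scores correlated with the first component at 0.773 and 0.739. No relation of the WNT score with an immune score was tested. Within groups the antimicrobial and WNT scores correlated at r = -0.723 (rho = -0.732, permutation p = 0.00016, adjusted p = 0.00024, r = -0.702 without control Mouse_26 and obese sulindac Mouse_124). The MHC class II and T and NK cell scores correlated at r = 0.931 (rho = 0.864, permutation p = 1e-05, the smallest the permutations can give, adjusted p = 3e-05, r = 0.889 without formerly obese Mouse_152 and obese Mouse_109). Sox2 and Cdx2 correlated at r = -0.310 (rho = -0.302, permutation p = 0.160, r = -0.164 without control Mouse_26 and obese Mouse_113), which leaves an opposition of foregut and intestinal identity open. The adjustment covers these 3 relations, and all 780 pairs of lists had been looked at before they were chosen, so the p values of the first 2 are too small by an amount that was not computed.

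The counts of 0 say nothing about chance, since every split gives at least as many. Of 100 splits into groups of the same sizes, the real one included, 100 gave at least the 0 genes called in each of the 6 comparisons and in the F test, and 100 at least the 0 lists called. The highest counts of genes among the other splits were 1 for obese against control, 1 for formerly obese against obese, 3 for obese sulindac against obese and 4 for formerly obese against control. For obese sulindac against control and for formerly obese against obese sulindac they were 19 and 21 against a real count of 0, which may point to a structure of the samples other than the 4 groups. Whether correlated noise alone gives such a highest count was not tested. For lists the highest others were 1, 2, 0, 5, 3 and 2 in the same order, and for the F test 1.

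Chance could not be excluded for the counts at an unadjusted p under 0.05. They were equalled or exceeded in 49 of 100 splits for obese against control (894 probe sets, highest other 2357) and in 23 for formerly obese against obese (1263, highest other 2367). The figures were 11 for obese sulindac against obese (1454, highest other 1926) and 49 for formerly obese against control (1231, highest other 2880). They were 14 for obese sulindac against control (1473, highest other 2296), 24 for formerly obese against obese sulindac (1470, highest other 2848) and 14 for the F test (1333, highest other 1846).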
